A study of Mus musculus with 12 samples.

How the data were processed

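Total RNA of 12 samples of caudate putamen from male C57BL/6J mice aged 12 weeks was hybridised to Illumina bead arrays, 1 array per sample. For 6 samples the mothers had been offered ethanol at 10% (v/v), which they drank by choice between day 0.5 and day 8.5 after mating, and 6 samples were controls, per the labels. The sample titles place the arrays on 2 chips, each holding 3 ethanol-exposed and 3 control samples, here called chip 1 and chip 2. Samples are named by their group and the replicate number in their title. The labels do not say that each sample came from its own mouse or litter, so that p-values measure the spread between these samples only.

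The deposited raw table holds 1 intensity per probe and array on a linear scale, not normalized between arrays, per the file headers and its values. Beside each intensity stands a detection p-value of the probe on that array, per the file headers. A second table deposited by the authors holds intensities on a linear scale whose quartiles and maximum are shared by all 12 columns, as quantile normalization gives. GenomeStudio 1.9.0 is listed in the submitters' processing notes. Its background setting, and any step that no header or label records, are not given in the sources used here.

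The raw intensities were background-corrected from the detection p-values, given an offset of 16, quantile normalized and taken to log2 with neqc of limma 3.58.1 in R 4.3.3. Of 45281 probes, 20296 (44.8%) had a detection p under 0.05 on at least 6 arrays, the size of 1 group, and were tested. GEO's platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378. The reference gene table (assembly GRCm38.p6) held the gene of 34807 probes and changed 0 symbols. The tested probes named 10933 genes. Probes with several symbols or none were tested and are not named. No genome build is stated for the arrays, so no coordinates are given.

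Arrays give no count of molecules, and their number limits the precision. The raw median intensity lay between 136.1 and 153.2 on the 12 arrays, and between 19452 and 21949 probes were detected. The median standard error of a log2 difference between the groups was 0.113, and 0.0791 and 0.174 at the 10th and 90th percentiles. The 2 most alike arrays differed by a root mean square of 0.272 log2 units, so no array was counted as a copy of another.

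Ethanol-exposed and control samples were compared per probe with lmFit and eBayes of limma over all 12 arrays, without covariates. The test was two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Differences are log2 ethanol minus control, with the standard error (SE) of the fit. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, on the brightest probe of each gene, adjusted over 39 lists. Camera with an estimated correlation and fry were run beside it, and the mean level of each list was compared by an exact permutation over the 462 splits of the 12 arrays into 2 groups of 6. The differences seen on chip 1 and on chip 2 were correlated across probes, with an exact permutation of the labels within chips over 400 labelings.

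The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, except for the exact permutation of list levels and the additions given below. The rule named 12 probes per direction, those past the threshold first and otherwise those with the smallest p, each named as not passing. It also named the 3 members of each list with the smallest p, and the fixed genes Slc17a6, Drd1, Drd2, Tac1, Penk, Pdyn, Adora2a, Ppp1r1b and Ttr. Xist and the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d were checks of the labels. Where a gene has several tested probes, the brightest stands for it in a list, and the text says where another probe differs in sign.

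The tests were run on simulated data built from the 20296 tested probes with 6 arrays per group. Over 5 runs, 250 probes each were changed by 1.25-, 1.5-, 2- and 3-fold. Called were 61.6% of probes changed 1.5-fold, 93.2% of those changed 2-fold and 11.2% of those changed 1.25-fold, and 33 of 100480 unchanged probes. Changed probes together ease the adjusted threshold, so a probe changed alone would be called less often than these shares. Of 100 unchanged gene sets 0 were called by camera, and of 5 sets of 30 genes shifted by 0.2 log2 units 5 were called. The simulated genes varied independently of each other.

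Alternatives were no background correction, an offset of 50, median scaling, cyclic loess, the authors' normalized intensities, no filter, a filter on all 12 arrays, and a detection p under 0.01. Further alternatives were chip as a block or a random block, each chip alone, replicate number as a block, eBayes with trend and robust, array weights, averaging a gene's probes, and leaving out each array in turn. Added after seeing the data were the exact permutation of list levels, a fit without ethanol 3 and ethanol 4, the samples correlating least with the rest, a fit with the level of thalamus genes as a covariate, and list tests with variances moderated over all probes. Correlations between list levels across samples were likewise not fixed beforehand. Figures were drawn with matplotlib 3.10.9.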

Results

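Gene expression was measured in the caudate putamen, the dorsal part of the striatum, of adult male mice whose mothers drank ethanol early in pregnancy, and in controls. Each group had 6 samples, with 3 per group on each of 2 array chips. The 12 arrays detected 19452 to 21949 of 45281 probes. The labels were checked with sex-linked genes. The 4 probes for Xist, the transcript that silences an X chromosome in females, were detected on 0 arrays. The brightest probes of the Y-linked Eif2s3y and Kdm5d were detected on 12 arrays and that of Uty on 11, while Ddx3y had no probe named in the annotation and was not analysed here.

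The first comparison asked which genes differ in the adult striatum after the early exposure. No probe passed the threshold. Of 20296 probes, 0 had an adjusted p under 0.05 in limma's test, the smallest adjusted p being 0.845. At an unadjusted p under 0.05 there were 1175 probes, 588 higher and 587 lower in ethanol-exposed mice, where chance gives 1014.8. With median scaling in place of quantile normalization the split was 336 higher and 678 lower. The 95% interval of the difference lay within 2-fold in either direction for 99.5% of probes and within 1.5-fold for 91.9%. In array signal, changes above those sizes were therefore excluded for these shares of probes, probe by probe, while smaller ones were not. The offset added before taking log2 makes differences of probes near background smaller, so larger changes in their transcripts are not excluded. How far signal follows transcript amount was not tested.

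None of the fixed genes that define striatal cells passed adjustment. Drd1, the dopamine receptor of direct pathway neurons, had a log2 intensity of 12.68 ± 0.13 in controls and 12.57 ± 0.17 in ethanol-exposed mice (SD, n = 6). Drd2, the receptor of indirect pathway neurons, had 10.68 ± 0.28 and 10.55 ± 0.26. Log2 differences were 0.13 (SE 0.12) for Tac1, −0.10 (SE 0.11) for Penk and 0.09 (SE 0.17) for Pdyn, which encode neuropeptide precursors. The dimmer Pdyn probe differed by 0.32 (SE 0.17). For Ppp1r1b, encoding the phosphoprotein DARPP-32, the difference was −0.17 (SE 0.09). Adora2a had no probe named in the annotation and was not analysed here. The adjusted p of these genes in limma's test lay between 0.854 and 0.972.

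The 12 probes with the smallest p among those higher in ethanol-exposed mice, none of which passed adjustment (adjusted p = 0.845 in limma's test), belonged to Celsr1, Lypd1, Necab1, Dnase1l2, Btla, Mtss1, Cd200, Edn1, Haus6, Nrxn2, Ifnar2 and P2rx7. Nrxn2, a presynaptic adhesion protein, was measured at 9.24 ± 0.15 in controls and 9.64 ± 0.19 in ethanol-exposed mice (SD, n = 6), with 1 of its 2 other probes of the same sign. Necab1, a neuronal calcium-binding protein, had 6.82 ± 0.23 and 7.26 ± 0.10. Edn1, the vasoconstrictor endothelin 1, had 7.04 ± 0.12 and 7.59 ± 0.34. The immune inhibitory ligand Cd200 had 6.91 ± 0.10 and 7.24 ± 0.13. Both other Cd200 probes, which were brighter, differed by only 0.01 (SE 0.08) and 0.04 (SE 0.11). The dimmer of 2 probes for Lypd1, an inhibitor of nicotinic receptors, differed by 1.03 (SE 0.22) and the brighter by 0.54 (SE 0.22). The named probe of Ifnar2 and its 1 other probe had opposite signs. Several of the 12 were near background. Celsr1 and Mtss1 were each detected on 1 control array, and on 6 and 5 ethanol arrays.

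The 12 probes lower in ethanol-exposed mice by the same rule, with the same adjusted p, belonged to Ankrd35, Zmat2, Nrn1l, Cdk19, Camk4, Taf1d, Kdm4b, Pcdhb20, Them6, Map7d2, Terf2 and Amz1. The brightest were Them6, at 12.62 ± 0.13 in controls and 12.27 ± 0.11 in ethanol-exposed mice, and Kdm4b, a histone demethylase, at 11.95 ± 0.05 and 11.64 ± 0.12 (SD, n = 6). In both, every ethanol-exposed sample lay below every control. Nrn1l, related to the growth-promoting neuritin, had 8.68 ± 0.13 and 8.23 ± 0.19. Camk4, a calcium-dependent protein kinase, had 6.55 ± 0.25 and 5.93 ± 0.27. Its other probe, far brighter at 12.74 in controls, differed by only −0.13 (SE 0.11). The named probes of Ankrd35, Cdk19 and Map7d2 were detected on 6 control arrays and 2 ethanol arrays each. The other Ankrd35 probe, which was brighter, differed by −0.01 (SE 0.11). Of other tested probes, 2 of 3 for Map7d2 and 1 of 2 for Terf2 had the opposite sign. Over all tested probes, 54 separated the groups fully, 32 with ethanol above and 22 below, where chance gives 43.9 (0.216%).

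**Figure D1:**
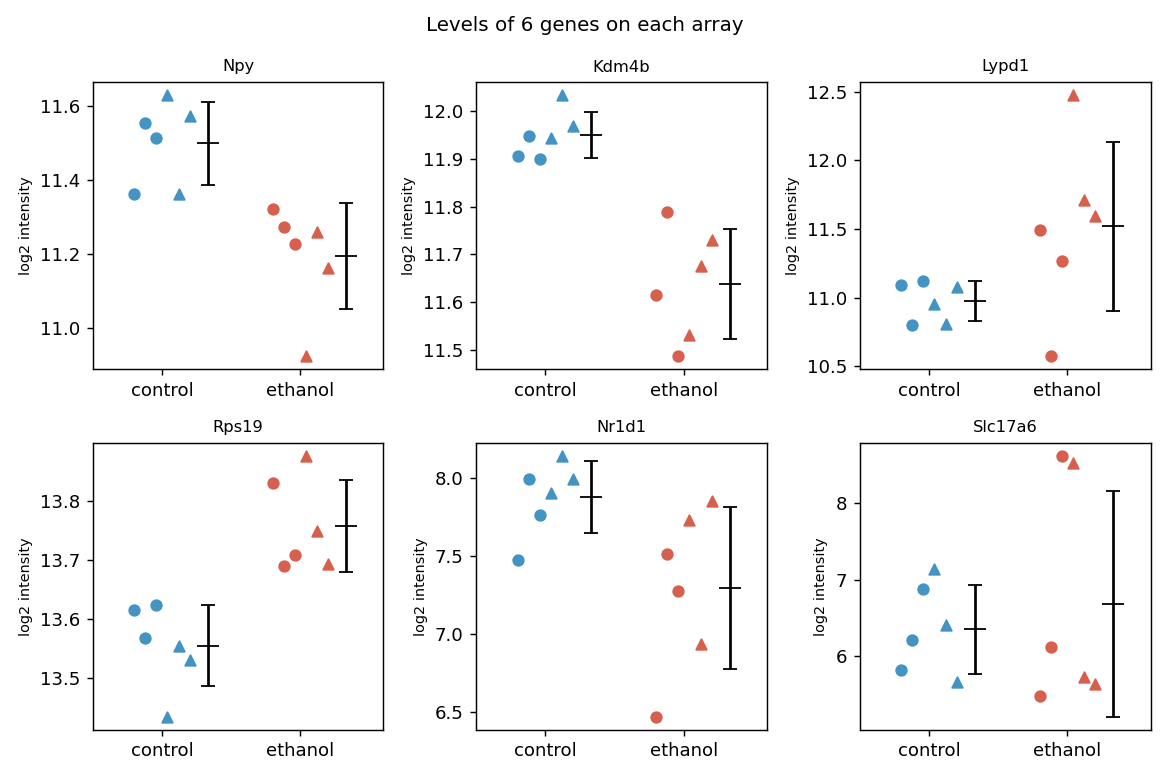
Log2 intensity of 6 genes on each array, brightest probe, with controls in blue and ethanol-exposed samples in red, circles for chip 1 and triangles for chip 2, and bars for mean and SD (n = 6). For Npy, Kdm4b and Rps19 the groups do not overlap, while Slc17a6 reaches 8.62 and 8.53 in ethanol 3 and ethanol 4 against 7.14 at most in the other samples.

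The second comparison asked whether groups of related genes were shifted. By camera with its preset correlation, 3 of 39 lists passed. Genes of striatal projection neurons were lower in ethanol-exposed mice as a group, with 22 of 27 tested members lower and a median log2 difference of −0.10 (camera adjusted p = 0.00199). The adjusted p was 0.943 with an estimated correlation, and the list level was 11.26 ± 0.08 in controls and 11.14 ± 0.16 in ethanol-exposed mice (SD, n = 6). Of its members, 0 passed the test over all probes and 0 passed adjusted over the list alone. The members with the smallest p were Dach1, a developmental transcription factor (−0.53, SE 0.16), Actn2, a cytoskeletal protein (−0.20, SE 0.09), and Cnr1, the cannabinoid receptor (−0.59, SE 0.27). The median was −0.15 on chip 1, −0.07 on chip 2 (adjusted p = 0.165 by camera) and, unchanged by the balanced design, −0.10 with chip as a block. It was −0.05 without ethanol 3 (adjusted p = 0.252) and −0.01 without ethanol 3 and ethanol 4 (adjusted p = 0.848). In those 2 samples the level of thalamus genes was 8.47 and 8.71, against 7.52 to 7.83 in the other samples.

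Genes of dopamine signalling, several of them shared with the preceding list, were lower in 14 of 19 tested members, with a median of −0.12 (camera adjusted p = 0.0343, and adjusted p = 0.686 with an estimated correlation). Th, the rate-limiting enzyme of dopamine synthesis, differed by −0.32 (SE 0.15) and Rasd2, a striatal small GTPase, by −0.20 (SE 0.10). Again 0 members passed over all probes and 0 adjusted over the list alone. The median was −0.12 on chip 1, −0.07 on chip 2 (adjusted p = 0.428 by camera) and, unchanged by the balanced design, −0.12 with chip as a block. It was −0.05 without ethanol 3 (adjusted p = 0.252), −0.11 without control 5 (adjusted p = 0.0591), −0.09 without control 6 (adjusted p = 0.0888) and −0.04 without ethanol 3 and ethanol 4 (adjusted p = 0.217).

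Genes of cytosolic ribosomal proteins were higher as a group, in 43 of 51 tested members, with a median of 0.09 (camera adjusted p = 1.69e-05, and adjusted p = 0.686 with an estimated correlation). The list level was 12.61 ± 0.03 in controls and 12.68 ± 0.04 in ethanol-exposed mice (SD, n = 6), and 5 of 6 ethanol-exposed samples lay above the highest control. Rps19 differed by 0.20 (SE 0.07), Rpl34 by 0.21 (SE 0.08) and Rpl31 by 0.23 (SE 0.09), all of them structural proteins of the ribosome, and 0 members passed over all probes or adjusted over the list alone. The 1 other tested probe of Rps19 and 1 of 2 other probes of Rpl31 had the opposite sign. The median was 0.06 on chip 1, 0.07 on chip 2 and, unchanged by the balanced design, 0.09 with chip as a block. The exact two-sided permutation p of the list level was 0.00433, or 0.169 adjusted over the 39 lists. By this test the adjusted p was 0.295 for dopamine signalling and 0.77 for striatal projection neurons. With fry's test for change in one direction or with an estimated correlation 0 lists passed, and 2 had an unadjusted p under 0.05 by each.

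**Figure D2:**
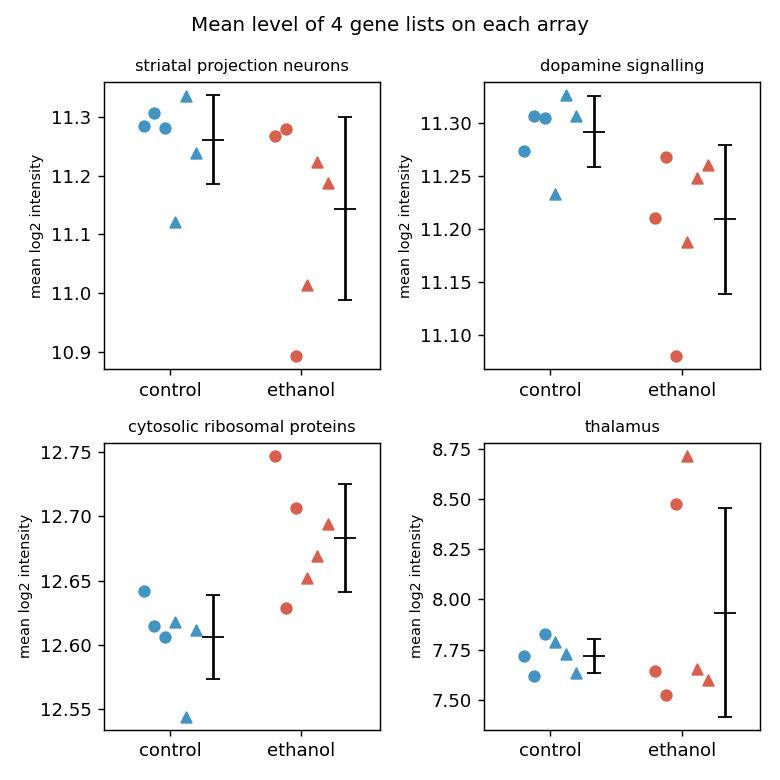
Mean log2 intensity of 4 gene lists on each array, with controls in blue and ethanol-exposed samples in red, circles for chip 1 and triangles for chip 2, and bars for mean and SD (n = 6). Ethanol 3 and ethanol 4 have the lowest levels of striatal projection neuron genes and the highest of thalamus genes, at 8.47 and 8.71.

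Other lists of striatal neurons did not pass. All 7 tested genes of the striosome compartment had higher values in ethanol-exposed mice, with a median of 0.13 (camera adjusted p = 0.0817), led by Lypd1 and by Tshz1 (0.39, SE 0.16). Their median was −0.11 on chip 1 and 0.37 on chip 2. The mean level of these striosome genes was highest in ethanol 4, at 10.79 against 10.52 at most in the other samples. Direct pathway genes had 5 of 8 higher (camera adjusted p = 0.997) and indirect pathway genes 3 of 6 (0.997). Of striatal interneuron genes, 12 of 17 were lower (camera adjusted p = 0.527). Within this list Npy, encoding neuropeptide Y, passed adjusted over the list alone and not over all probes, at 11.50 ± 0.11 in controls and 11.20 ± 0.14 in ethanol-exposed mice (SD, n = 6), lower in 6 of 6 samples than in any control.

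Lists of cells and regions that a striatal dissection can hold did not pass either. Oligodendrocyte genes were lower in 18 of 19 members, with a median of −0.14 (camera adjusted p = 0.0563). The median was 0.30 on chip 1 and −0.59 on chip 2, opposite in sign, but 0.10 on chip 1 without ethanol 3, and −0.34 and −0.42 on chip 2 without ethanol 4 or control 4. Genes of the neurogenic niche, such as Dlx2 (0.61, SE 0.24) and Dcx (0.32, SE 0.15), were higher in 9 of 11 (camera adjusted p = 0.077), while the 1 other tested probe of Dlx2 had the opposite sign. Their median was 0.05 on chip 1 and 0.50 on chip 2. Thalamus genes were higher in 7 of 9, with an adjusted p of 0.323, and Slc17a6, a vesicular glutamate transporter, differed by 0.33 (SE 0.54). Members higher numbered 14 of 20 for astrocytes, 9 of 19 for microglia and 10 of 19 for vascular cells (camera adjusted p of 0.581, 0.375 and 0.599). They numbered 5 of 10 for oligodendrocyte precursors, 7 of 11 for ependyma and 2 of 4 for choroid plexus (0.997, 0.994 and 0.997). They numbered 3 of 7 for meninges, 3 of 6 for red blood cells, 3 of 10 for cortical excitatory neurons and 2 of 5 for septum and pallidum (0.997, 0.884, 0.176 and 0.527). For septum and pallidum the median was −0.07, while the mean level differed by 0.11 in the other direction. Ttr, the main choroid plexus transcript, had an SD above the difference between groups, at 8.35 ± 2.23 in controls and 8.89 ± 2.14 in ethanol-exposed mice.

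Among lists of signalling and response genes, the circadian clock list was lower in 10 of 14 members (median −0.17, camera adjusted p = 0.077). The median of this list was −0.06 on chip 1 and −0.34 on chip 2. The clock genes with the smallest p were the repressor Nr1d1 (−0.59, SE 0.20), the output factor Dbp (−0.49, SE 0.21) and Ciart (−0.93, SE 0.39). Glucocorticoid response genes were lower in 13 of 19 (median −0.12, camera adjusted p = 0.0563), with Cdkn1a at −0.34 (SE 0.11), and their median was 0.14 on chip 1 and −0.29 on chip 2. Immediate early genes were lower in 12 of 18 (camera adjusted p = 0.195) and inflammatory genes in 9 of 11 (0.195). In the neurotrophic and growth factor list 7 of 16 were higher (camera adjusted p = 0.975). Of these, 4 passed adjusted over the list alone and 0 over all probes, in both directions. They were Egfr (0.28, SE 0.09) and Vegfa (0.33, SE 0.11), with higher values, and Tgfb1 (−0.39, SE 0.12) and Igfbp4 (−0.32, SE 0.11, named after its values were seen), with lower ones. For Egfr 1 of 3 other tested probes had the opposite sign. The dimmer Vegfa probe ran from 7.44 to 7.82 in ethanol-exposed samples and from 7.31 to 7.82 in controls. Tgfb1 was at 5.17 to 5.28 in ethanol-exposed samples and 5.82 to 6.03 in controls on chip 1. On chip 2 its levels overlapped, at 5.53 to 5.76 and 5.63 to 5.91. Fry's test for change in either direction gave this list an adjusted p of 0.0247 and the ribosomal list 0.00926.

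Lists of neurotransmission did not pass. Members higher numbered 17 of 29 for glutamate transmission, 10 of 14 for GABA transmission, 3 of 5 for opioid peptides and receptors and 7 of 20 for synaptic vesicle release (camera adjusted p of 0.997, 0.467, 0.997 and 0.331). Lists tied to the exposure by known chemistry were likewise not called. Ethanol and aldehyde metabolism had 4 of 9 higher (camera adjusted p = 0.503), one-carbon metabolism 9 of 13 (0.375), DNA methylation and chromatin 19 of 34 (0.581) and imprinted genes 13 of 26 (0.997). Antioxidant defence had 10 of 26 higher (0.997), and the retinoic acid pathway 6 of 10 (0.785). The unfolded protein and heat shock list had 11 of 25 higher (0.503), and within it the stress-induced pseudokinase Trib3 differed by 0.68 (SE 0.19). Interferon response genes had 9 of 19 higher (0.85), mitochondrial respiratory chain genes 55 of 70 (0.077) and cholesterol synthesis genes 8 of 16 (0.997).

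**Figure D3:**
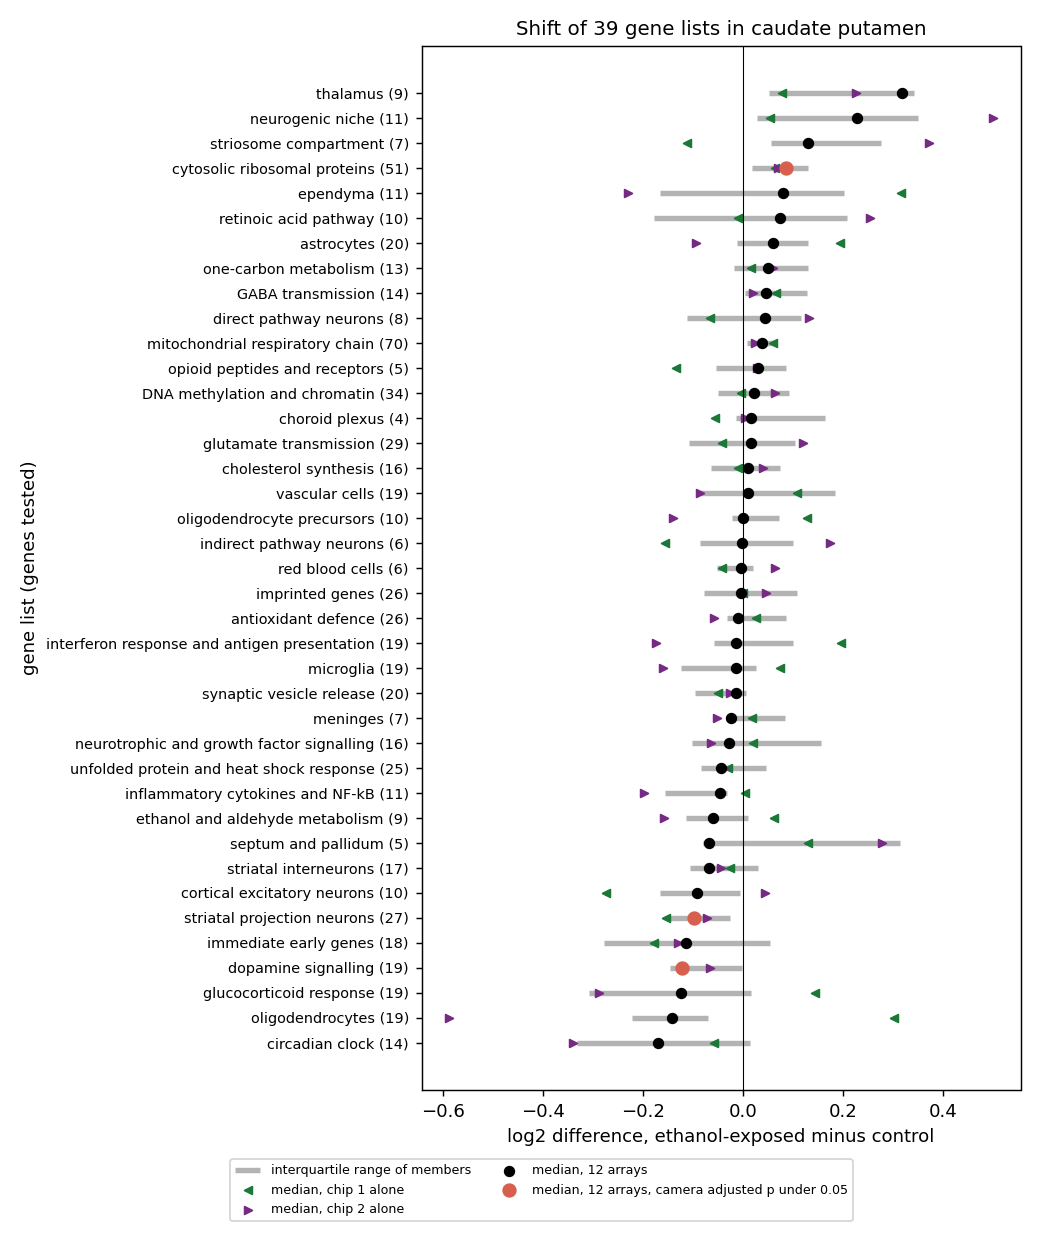
Median log2 difference, ethanol-exposed minus control, of 39 gene lists, with the interquartile range of members as a grey bar and the medians on chip 1 and chip 2 as triangles. The 3 lists past the camera threshold are in red, with medians of −0.12, −0.10 and 0.09, and oligodendrocyte genes lie at 0.30 on chip 1 and −0.59 on chip 2.

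The third comparison set the samples of chip 1 against those of chip 2, each with its own controls. The log2 differences were not positively correlated. Across 20296 probes, which are not independent replicates, Pearson's r was −0.12 (one-sided exact permutation p = 0.77) and Spearman's rho −0.11 (p = 0.76, exact permutation). Without control 4, r was 0.0184. The r over all 400 labelings ran from −0.27 to 0.27. Lypd1 and Dach1 show how single genes compared. The brighter Lypd1 probe differed by 0.11 on chip 1 and 0.98 on chip 2, and Dach1 by −0.52 and −0.54. Group membership took 9.82% of the variance, where 9.09% is expected of random groups, and chip took 11.8%.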

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

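Among the tests in this part, those on ethanol 3 and ethanol 4 as samples, on the splits for single gene lists and on the splits for probes past adjustment were chosen after the result was seen. Each group of 6 samples was screened for a sample far from the rest, by its gap to the nearest other over the whole range of the group, for 27 genes, 39 list levels and 3 array measures. Of 138 groups, 11 held such a sample, and chance flags about 1 in 20. Low samples were control 1 for Cd200 (6.70 against 6.92 to 6.99), ethanol 2 for Ifnar2 (6.00 against 6.33 to 6.53) and control 4 for Drd2 (10.12 against 10.72 to 10.94). Control 4 was high for oligodendrocyte genes (11.88 against 11.08 to 11.34) and for interferon response genes (8.09 against 7.54 to 7.70). Ethanol 3 was high for striatal interneuron genes (8.82 against 8.45 to 8.55) and for oligodendrocyte precursor genes (8.18 against 7.75 to 7.85). Cortical excitatory neuron genes were high in control 2 (8.50 against 7.69 to 7.89) and in ethanol 4 (8.09 against 7.60 to 7.77). Glucocorticoid response genes were high in ethanol 2 (8.91 against 8.22 to 8.41), and ribosomal protein genes were low in control 5 (12.54 against 12.61 to 12.64).

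Other splits of the 12 samples show what chance gives. With 0 probes past adjustment in the real split, each of 100 splits, the real one included, reached that count by construction (100 of 100, highest other 10), which says nothing about chance. At an unadjusted p under 0.05, 34 of 100 splits gave as many as the real 1175 probes, the highest other giving 2527. For gene lists past the camera threshold, 80 of 100 splits gave as many as the real 3, with 14 as the highest and 6 as the median of the others. With chip as a block, among 100 splits balanced over the chips, 23 gave as many as the real 1318 probes (highest other 2021) and 81 as many as the real 3 lists (highest other 16). Chance is excluded for none of the counts at an unadjusted p or of lists, and a preset correlation of 0.01 called lists in most splits that follow no treatment.

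The lower level of striatal projection neuron genes in ethanol-exposed mice rested on ethanol 3 and ethanol 4. The mean difference of the list was −0.117 (SE 0.0706) over 12 arrays and −0.0222 (SE 0.0371) without both, where the camera call ended because the difference itself shrank. Of 462 splits, 64 gave a difference of mean level as large as the real 0.117 in either direction, with 0.179 as the highest other, so chance is not excluded. Both were the lowest of 12 samples for this list (10.89 and 11.01, others from 11.12), so leaving them out shrinks the difference whatever the cause, and neighbouring tissue in their dissected pieces cannot be told apart from any other property of the same samples. For dopamine signalling, 7 of 462 splits reached the real difference of 0.0825 (highest other 0.0941), a share that does not allow for the choice among 39 lists. Ethanol 3 and ethanol 4 were again the lowest (11.08 and 11.19, others from 11.21), and the median of −0.12 was −0.0379 without both and −0.0507 with the thalamus covariate. Neighbouring tissue and prenatal ethanol stay open for this list, both untested.

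Ethanol 3 and ethanol 4 themselves correlated least with the other arrays, at a mean of 0.984 and 0.983. Slc17a6, Calb2, Prkcd and Cacna1g, all from the list of 9 tested thalamus genes, lay above all 10 other samples in both. Of the 9 genes, 6 did so in ethanol 4 and 4 in ethanol 3, fewer in ethanol 3 than a majority, which neighbouring tissue was taken to need. This count cannot decide, since it ignores the size of each gap. In ethanol 3, Tcf7l2 missed at 8.24 against 8.29 in control 4, while Slc17a6 was at 8.62 against 7.14 at most. Ntng1 and Rora lay above all others in neither sample. Both were also the 2 highest of 12 samples for septum and pallidum genes (7.43 and 7.61, others up to 7.19) and choroid plexus genes (8.48 and 8.10, others up to 7.87), lists of 5 and 4 tested genes, and for GABA transmission and imprinted genes, 5 of 39 lists in all with thalamus. They were the 2 lowest for 3 lists, striatal projection neurons, dopamine signalling and the retinoic acid pathway. The septal and choroid plexus values go with neighbouring tissue, but Ttr was at 10.31 in ethanol 4 and 10.35 in control 4. In other lists the 2 samples parted. For oligodendrocyte genes ethanol 3 was the highest of 12 samples (11.91) and ethanol 4 the lowest (10.56). For direct pathway genes ethanol 3 was the lowest (10.40) and ethanol 4 the highest (10.63). Ethanol 4 was also the lowest for ependyma genes (6.77, others from 7.07). The GABA and imprinted lists were not fixed as region markers, but their genes can differ between regions, and Dlk1 is in both the imprinted and septal lists. Their rise therefore does not argue against neighbouring tissue. Whether such tissue was the source cannot be told apart from other differences between these samples. Poor hybridisation is argued against for ethanol 3 by its 21526 detected probes, above the median of 20347 of the 10 others. It stays open for ethanol 4, whose 19963 lay below that median and above the lowest of the others, 19452. Ethanol 2, ethanol 5, ethanol 6 and control 1 had fewer detected probes than ethanol 4 and correlated better, at 0.987 to 0.989. Calb2 also marks striatal interneurons, and Cartpt, outside the list and chosen after its values were seen, was at 12.09 in ethanol 4 and from 6.20 to 8.24 elsewhere.

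The higher level of ribosomal protein genes in ethanol-exposed mice did not rest on any single array, with medians of 0.07 to 0.10 as each was left out. A shift of all bright probes left by the normalization is argued against, since the median of 0.09 lay above all of 10000 random lists of the same size and brightness (percentile 100, highest random median 0.04). Of 462 splits, 2 reached the real difference of mean level of 0.0769, with 0.0813 as the highest other, which excludes chance for this list taken alone but not after adjustment over the 39 lists (adjusted exact permutation p = 0.169). Differences in RNA handling between the samples were not tested. Prenatal ethanol also stays among the open explanations, untested.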

How the results depend on the processing

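The fits without ethanol 3 and ethanol 4, with thalamus gene level as a covariate and with list variances moderated over all probes were chosen after seeing the data. In every fit per probe 0 probes passed adjustment, and the smallest adjusted p without 1 array ran from 0.335 to 0.946. The count at an unadjusted p under 0.05 was 1013 to 1531 without 1 array, 2420 with no filter, where more probes are tested, 642 with a gene's probes averaged, where fewer features are, and 2051 on chip 2 alone. The number of lists past the camera threshold, 3, moved most. It was 9 with no background correction, an offset of 50, the authors' values, trend and robust, or chip 1 alone, and 10 on chip 2 alone. It was 8 with no filter or averaged probes, 6 with median scaling or a detection p under 0.01, and 5 with cyclic loess, detection on all 12 arrays, chip as a random block, array weights or variances moderated over all probes. It was 2 to 8 without 1 array, and 0 with an estimated correlation and with fry's test for one direction. The cause was not tested. In their deviations from the group means, same-numbered samples correlated at −0.14 to 0.28, and 2 of 6 ethanol samples matched their own number best. These values do not decide whether the replicate numbers pair the samples. With the replicate number as a block 1425 probes had an unadjusted p under 0.05, 0 passed adjustment and 5 lists passed.

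Ribosomal protein genes kept their direction in 33 alternatives and their call in 31, losing it at 0.0862 with an estimated correlation and with fry. Some alternatives cannot change a list's median, so the direction was fixed there. These are the chip and replicate blocks, trend and robust, variances moderated over all probes, an estimated correlation and fry. Striatal projection neuron genes kept their direction in all 33 and their call in 27. Where the call was lost the median was −0.0729 on chip 2, −0.0468 with the thalamus covariate, −0.0091 without ethanol 3 and ethanol 4, and −0.0988 with an estimated correlation and fry. Without 1 array it ran from −0.131 to −0.0481, the call being lost without ethanol 3. Dopamine signalling kept its call in 24 of 33. Where the call was lost its median was −0.0740 with no filter, −0.0660 on chip 2, −0.0507 with the covariate, −0.0379 without ethanol 3 and ethanol 4, and −0.123 with an estimated correlation and fry. Without 1 array it ran from −0.129 to −0.0493, the call being lost without ethanol 3, control 5 or control 6. Over the alternatives the adjusted p ran up to 0.951 for striatal projection neurons, 0.717 for dopamine signalling and 0.686 for ribosomal proteins. The other 36 lists, set against the alternatives 1186 times, passed 90 times in the direction of their median, with 17 for oligodendrocytes, 15 for glucocorticoid response, 14 for circadian clock, 12 for mitochondrial respiratory chain and 12 for neurogenic niche. Oligodendrocytes and neurogenic niche passed also without ethanol 3 and ethanol 4, and the latter with the covariate. Those calls used the preset correlation of 0.01. Over 12 arrays the estimated correlation was 0.855 and 0.332, with camera adjusted p of 0.963 and 0.943. The adjusted exact permutation p was 0.935 and 0.77. Of the 36 lists, 3 passed on 1 chip against the sign of their median over 12 arrays, oligodendrocytes (0.302) and interferon response (0.196) on chip 1 and astrocytes (−0.0943) on chip 2. For interferon response the median (−0.0138) and mean (0.0264) over 12 arrays differ in sign. The correlation of the chips' effects ran from −0.204 to 0.0184 without 1 array, above 0 only without control 4. The 145 named probes were set against the alternatives 4300 times, passed adjustment in 0 and had the other sign in 59. Signal over background limits the dimmest of them, such as Celsr1 and Mtss1, detected on 1 control array each.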

Other observations

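Large differences between samples in Ttr, Igsf1 and Npas4 did not follow the exposure. Ttr, the transthyretin of the choroid plexus, ran from 5.44 in control 1 to 12.43 in ethanol 3 (log2 intensity), and Igsf1 from 5.05 in ethanol 5 to 9.61 in ethanol 3. The activity-dependent gene Npas4 ran from 5.86 in ethanol 3 to 8.73 in ethanol 6, with 8.69 in control 6. Ciart, of the circadian clock, was above 10 in ethanol 2 and in 4 controls, namely control 2, 4, 5 and 6, at 10.24 to 10.50, and between 8.11 and 9.25 in the others, with a difference between the groups of −0.93 (SE 0.39). Igsf1 and Npas4 were chosen after their values were seen.

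The pseudogenes Pisd-ps1 and Pisd-ps3, chosen after their values were seen, were among the 5 probes that differed by more than 1 log2 unit. Pisd-ps1 was at 8.98 ± 0.58 in controls and 10.02 ± 0.54 in ethanol-exposed mice, and Pisd-ps3 at 10.31 ± 0.61 and 11.41 ± 0.59 (SD, n = 6). Both had an adjusted p of 0.845 in limma's test. Transcripts of such copies can share sequence, so the probes may not be independent measurements, which was not tested.

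The mean level of oligodendrocyte genes differed between ethanol-exposed and control mice by 0.30 on chip 1 and by −0.57 on chip 2, a contrast with an exact permutation p of 0.015 over 400 labelings, or 0.351 adjusted over 39 lists. Single samples carried much of it. Without ethanol 3 the difference on chip 1 was 0.07, and on chip 2 it was −0.37 without ethanol 4 and −0.38 without control 4. Of 20296 probes, 0 differed in effect between the chips after adjustment in limma's test. At an unadjusted p under 0.05 there were 2026, where chance gives 1014.8 if probes are independent. No relabelling was run for this count. For the difference between groups, other splits of the samples gave up to 2527 such probes. That is a different contrast, so whether chance gives 2026 here was not decided.

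Across the 12 samples the level of thalamus genes was correlated with that of striatal projection neuron genes at r = −0.837 (permutation p = 0.0094) and rho = −0.357 (permutation p = 0.256). This was 1 of 2 relations computed, and the adjusted p of r was 0.0188. Within chips r was −0.953 and −0.778. Without the 2 samples farthest from the median of the striatal list r was −0.12, so the relation rests on those samples. For oligodendrocyte genes r was −0.267 (permutation p = 0.386) and rho −0.189 (permutation p = 0.558), with r at −0.961 on chip 1 and 0.385 on chip 2, and −0.599 without the same 2 samples.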
